A study of Mus musculus with 16 samples.

How the data were processed

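Small RNA of mature mouse sperm was measured in 8 libraries, and gene expression was measured in 8 libraries of 3T3 cells, a mouse fibroblast line. Per the labels' protocols, sperm were collected from the cauda epididymis of males that lacked or kept Dnmt2 (Trdmt1), a tRNA cytosine methyltransferase, after a high-fat diet (HFD) or a normal diet (ND). RNA was extracted with Trizol, and libraries were made with the TruSeq small RNA kit. Per the labels' protocols, 3T3 cells received 100 nM of a synthetic fragment of glycine tRNA (tsRNA-Gly) with 0, 4 or 5 methylated cytosines (m5C), or the transfection reagent without RNA ("empty"). The sample titles name the fragment 3'tsRNA-Gly. The medium was changed after 4.5 h and the cells were harvested at 12 h.

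The deposited sperm values are counts: each file lists distinct read sequences with their length and their number of reads, and no header. The sequences in the files were 18 to 44 nt long. The trimming of adapters is not given in the sources used here. The deposited 3T3 values are estimated counts and TPM per transcript; kallisto made them, per the submitters' processing notes, with no version given. Estimated counts were rounded to whole numbers and used for all tests. The deposited TPM values were not used in a test. The builds mm10 and GRCm38 are named in the submitters' processing notes, and no coordinates were used here.

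No genome, small RNA annotation or transcript-to-gene table was used here. None of the 109282 transcript IDs of the 3T3 files was found in the gene tables, so transcripts are given by ID, and the tests of gene lists planned for 3T3 cells were not run. Sperm reads were assigned with sequences written from memory. The 11 tRNA sequences were written before the data were examined. The 6 rRNA pieces, 62 mature microRNA arms and 1 mitochondrial tRNA were written afterwards, so families of rRNA and microRNA are an addition to the plan, which had limited the families to tRNA. The sequences were checked by read coverage alone: reads covered every base of the 11 tRNAs and 3272 of the 3288 rRNA bases, and 61 of the 62 arms were detected.

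A read was assigned to a family when it matched a listed sequence without a mismatch. A tRNA fragment (tsRNA) was called 5' when it started within the first 3 bases, 3' when it reached the end of the tRNA, and internal otherwise. Reads shared by the AAC and CAC valine tRNAs formed a family of their own. A microRNA read had to begin with the first 20 nt of the arm and be at most 26 nt long. These rules assigned 46.9% to 53.8% of the reads of a library; 65.2% to 69.6% were assigned with up to 1 mismatch. Abundances are counts per 1000000 reads of the library (CPM), and the share of a class is a percentage of all reads.

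Depth ranged from 10165031 to 19030258 reads in sperm and from 16326238 to 27014080 estimated counts in 3T3 cells. A count of 0 in a sperm library allows up to 3 counts, or 0.158 to 0.295 CPM. The 95% Wilson interval of a class share was at most ± 0.0282 percentage points wide. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

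Samples were grouped by the labels, with 2 libraries in each of 4 sperm and 4 3T3 groups. The labels do not say that replicates were separate animals or cultures, so p-values measure the spread between libraries, which may be technical. No replicate pair agreed within counting noise (chi-square per feature of 8.32 to 11.1 in 3T3 and 39 to 379 in sperm), so none was counted as 1 library. Replicate numbers were tested for pairing before the fits were compared, and they did not pair the libraries.

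Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the 4 groups of an experiment in one fit. Libraries were scaled by TMM, and features were kept by filterByExpr; a Benjamini-Hochberg adjusted p under 0.05 was called. Sperm reads were tested per distinct sequence (50458 kept) and per family, where the total of reads was the library size and no further factor was applied. Shares were compared by two-sided exact permutation of 4 libraries against 4, which cannot go below p = 0.0286, adjusted over 8 tests. With 2 libraries against 2 such a test cannot go below 0.333, so those values carry no test. Figures were drawn with matplotlib 3.10.9.

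The groups, tests, other settings and the rule for named items were fixed before the data were examined. For 3T3 the rule named the 10 largest rises and falls past the threshold, or the 5 genes of lowest p where none passed, and Trdmt1 and Nsun2. Without gene names only the 2 transcripts that passed are given, by ID. For sperm it named families past the threshold, the fragments of tRNA-Asp-GTC, tRNA-Gly-GCC, tRNA-Val-AAC, tRNA-Glu-CTC, tRNA-Lys-CTT and tRNA-His-GTG, the rRNAs, and the 3 most abundant members of each microRNA list. It also named the 5 most abundant sequences and, where no sequence passed, the 3 with the lowest p of each comparison. Not all of the sequences this rule takes are given in the text. Unmatched sequences are given by length and value only. The microRNA lists were germline and sperm, let-7, epididymal epithelium, blood, endothelium, muscle and liver. Settings fixed beforehand as alternatives were DESeq2 1.42.0, other scalings and filters, matching with 1 mismatch, a replicate block, and leaving out each library in turn.

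Sperm libraries were also compared by the errors of their reads, after the data were examined. Among the 3000 most abundant sequences, those with over 300 reads in every library were used to compute the median rate of each substitution at each base of the read. The sperm libraries fell into 3 sets by 2 of these rates, and the set served as a batch. Further alternatives chosen after seeing the data were the set as a term, the removal of both libraries of set C, and matching with 1 substituted, inserted or deleted base. Sets A and B each held libraries of 1 diet only. With the set as a term, diet differences therefore rest on the 2 libraries of set C, and without set C diet and set coincide.

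The edgeR steps were tested on simulated counts with 200 changed features. For 3T3 5 x m5C against empty, with 44374 transcripts, 0%, 14%, 24% and 32% of changes of 1.5, 2, 4 and 8 fold were recovered, with 2 false calls. For HFD against ND in Dnmt2+/+ sperm, with 50458 sequences, none of the changes of 2, 4, 8 or 16 fold was recovered at the fitted spread. With the spread between sets removed, 0%, 2%, 16% and 36% were recovered. For the 34 tRNA families of the same comparison, 6%, 18%, 40% and 70% were recovered at the fitted spread over 25 simulations, with 6 false calls. With the spread between sets removed, 18%, 74%, 98% and 100% were recovered, with 9 false calls.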

Results

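Small RNA was sequenced from cauda sperm of Dnmt2+/+ and Dnmt2-/- mice on ND or HFD, with 2 libraries per group. The series title names paternally acquired metabolic disorders and sperm small RNA, and the comparisons ask how diet and loss of Dnmt2 change that RNA. The Dnmt2+/+ ND libraries held 19030258 and 13649529 reads, and the Dnmt2+/+ HFD libraries held 10296280 and 10165031. The Dnmt2-/- ND libraries held 13181541 and 13150403 reads, and the Dnmt2-/- HFD libraries held 10305631 and 13305449. The 8 libraries of transfected 3T3 cells held 16326238 to 27014080 estimated counts, again with 2 libraries per group. The knockout itself was not checked, since small RNA reads measure neither Dnmt2 mRNA nor m5C.

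Among the most abundant sequences of sperm small RNA were 5' fragments of tRNA-Gly-GCC. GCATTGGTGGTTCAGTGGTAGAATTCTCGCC and GCATTGGTGGTTCAGTGGTAGAATTCTCGC averaged 53284 and 30416 CPM over the 8 libraries.

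The sperm libraries differed in a way that the groups do not explain. The median rate of G-to-T changes at base 29 of the read was 403 and 465 per 10000 in replicate 1 of Dnmt2+/+ ND and of Dnmt2-/- ND, and 384 in Dnmt2-/- ND replicate 2. It was at most 2.48 in the other 5. The rate of C-to-G changes at base 26 was 9.74, 9.98 and 9.09 per 10000 in both Dnmt2+/+ HFD libraries and Dnmt2-/- HFD replicate 1, and 0 elsewhere. These libraries are called sets A and B, and the remaining Dnmt2+/+ ND replicate 2 and Dnmt2-/- HFD replicate 2 are set C. Set A thus held ND libraries only and set B HFD libraries only, so that diet can be compared within set C alone, with 1 library of each diet that also differ in genotype.

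**Figure D1:**
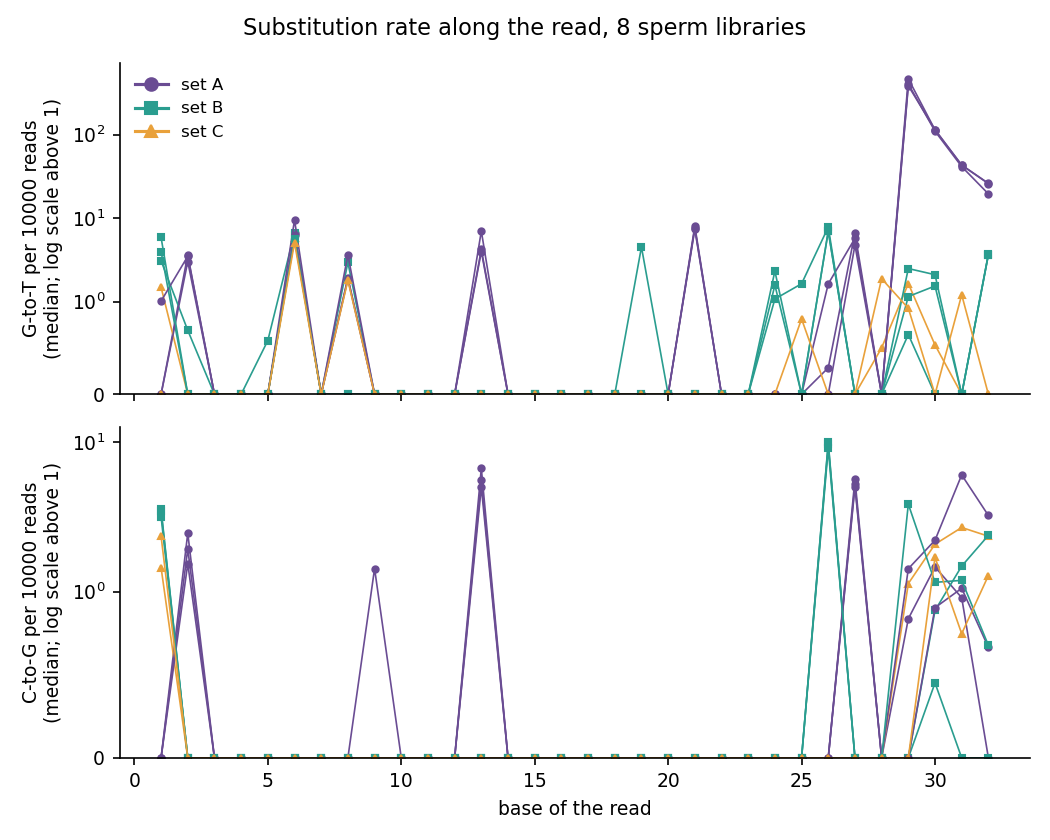
Median rate of G-to-T (top) and C-to-G (bottom) substitutions per 10000 reads at each base of the read, 1 line per sperm library, on an axis that is linear up to 1 and logarithmic above. The 3 libraries of set A stand apart at base 29, with 384 to 465 against at most 2.48, and the 3 of set B at base 26 in the lower panel, with 9.09 to 9.98 against 0.

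Across the 50458 tested sequences, log2 CPM of libraries of the same set correlated with a mean r of 0.891 over 7 pairs, and of different sets with 0.663 over 21 pairs. Sequences are not independent replicates. The 5 pairs of the same set and different groups had r of 0.849 to 0.929. Of these, 1 also differed in diet, the pair of set C with r of 0.849, and the others shared the diet. The tested sequences include reads with the errors that define the sets, which can raise r within a set. The 2 pairs of the same group and different sets had r of 0.606 and 0.765.

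The tsRNA share of sperm reads was 40.2% ± 4.14 (SD, n = 4) on ND and 27.9% ± 4.44 (SD, n = 4) on HFD. Dnmt2+/+ sperm held 39.3% ± 6.92 on ND and 24.2% ± 1.82 on HFD, and Dnmt2-/- sperm held 41.1% ± 0.133 and 31.6% ± 0.981 (SD, n = 2 each). All 4 ND libraries lay above all 4 HFD libraries, and the difference was -12.3 percentage points (exact permutation p = 0.0286, the smallest this design can give; adjusted p = 0.114 over 8 tests). The test did not pass after adjustment. The difference was -15.7 points among replicates numbered 1 and -8.88 among those numbered 2. In set C the ND library held 34.4% and the HFD library 32.3%. This gap depended on the match rule: with up to 1 mismatch these libraries held 49.3% and 40.9%. With 1 substituted, inserted or deleted base allowed, they held 60.3% and 52.8%. With the set as a term, the difference for exact matches was -3.89 points. That value is the difference between the same 2 libraries of set C, corrected for genotype, and no separate support.

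Reads of 30 to 34 nt, the length of most 5' tsRNA, made up 68.8% ± 3.29 on ND and 56.3% ± 4.11 on HFD (SD, n = 4 each). The difference of -12.5 points had the same permutation p of 0.0286 and adjusted p of 0.114. The rRNA-derived share was 9.67% ± 2.94 on ND and 16.2% ± 4.09 on HFD, and the microRNA share was 1.73% ± 0.742 and 5.04% ± 1.85 (SD, n = 4 each). Their exact permutation p was 0.0857 and 0.0571, with adjusted p of 0.171 and 0.152. In set C, the HFD library held more rRNA-derived reads (19% against 13.1%) and more microRNA reads (2.47% against 1.97%), and fewer reads of 30 to 34 nt (58.4% against 64.4%). With the set as a term, the differences were 8.18 points for rRNA, 1.34 for microRNA and -10.7 for reads of 30 to 34 nt. These again restate the difference between the libraries of set C, corrected for genotype.

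**Figure D2:**
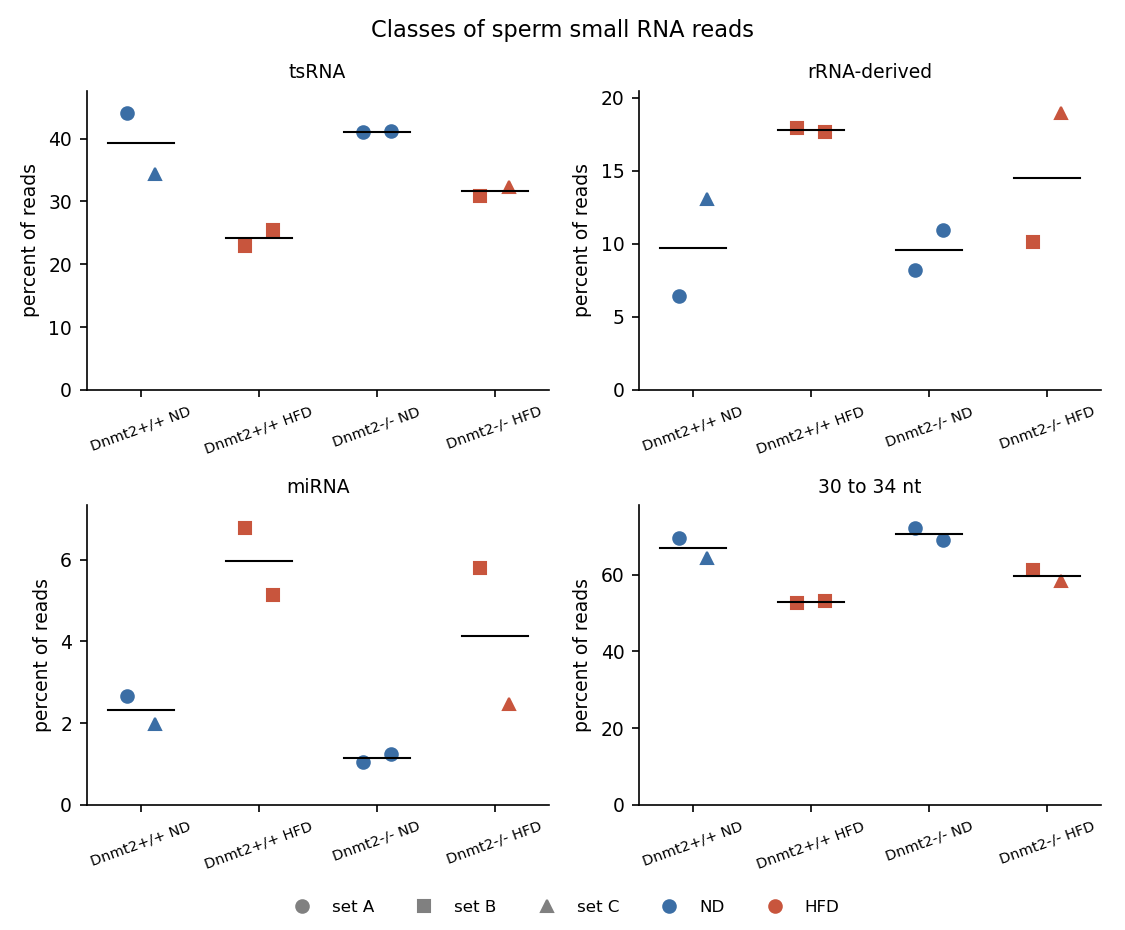
Percentage of sperm reads that were tsRNA, rRNA-derived, microRNA and 30 to 34 nt long, 1 point per library and a line at the mean of each group of 2. Color gives the diet and shape the set; the 4 ND libraries lie above the 4 HFD libraries in tsRNA share and in reads of 30 to 34 nt.

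Over both diets, genotype moved these shares less than the libraries spread, and that spread includes the difference between the diets. The tsRNA share was 31.7% ± 9.61 in Dnmt2+/+ and 36.4% ± 5.52 in Dnmt2-/- sperm (SD, n = 4 each; exact permutation p = 0.4, adjusted p = 0.457). Reads of 30 to 34 nt made up 59.9% ± 8.38 and 65.2% ± 6.54 (exact permutation p = 0.371, adjusted p = 0.457). The rRNA-derived share was 13.8% ± 5.39 and 12.1% ± 4.75 (exact permutation p = 0.657), and the microRNA share 4.14% ± 2.23 and 2.63% ± 2.2 (exact permutation p = 0.286). On HFD alone, the tsRNA share was 24.2% ± 1.82 in Dnmt2+/+ and 31.6% ± 0.981 in Dnmt2-/- sperm. Reads of 30 to 34 nt made up 52.9% ± 0.379 and 59.7% ± 1.96 there (SD, n = 2 each). On HFD the genotypes did not overlap in these 2 shares, and on ND they did, without a test. Within sets the genotype difference in tsRNA share went both ways. Dnmt2-/- minus Dnmt2+/+ was -3.02 points in set A, on ND, and 6.71 in set B, on HFD.

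The comparison of HFD with ND in Dnmt2+/+ sperm asks how diet changes sperm small RNA with Dnmt2 present. 5' fragments of tRNA-Glu-CTC were at 239900 CPM ± 137200 on ND and 138800 ± 3747 on HFD (SD, n = 2 each; log2 fold change -0.79 ± 0.42 SE). Those of tRNA-Gly-GCC, a DNMT2 substrate, were at 139000 ± 57080 and 81050 ± 12450 (log2 fold change -0.78 ± 0.48 SE). 5' fragments that match tRNA-Val-AAC alone, another substrate, had a log2 fold change of 2.56 ± 1.16 SE. They were scarce, at 34.13 CPM ± 43.95 on ND and 201.6 ± 33.28 on HFD (SD, n = 2 each). Those shared with tRNA-Val-CAC were at 3425 ± 1677 and 7658 ± 512.8, with a log2 fold change of 1.16 ± 0.88 SE (not passed). Values given below for tRNA-Val-AAC are of the scarce reads alone. 3' fragments of tRNA-Lys-CTT had a log2 fold change of 2.32 ± 1.16 SE. None of the 34 tRNA families passed (edgeR quasi-likelihood, lowest adjusted p = 0.523), with 2 at an unadjusted p under 0.05; families were not run in DESeq2. Without Dnmt2+/+ ND replicate 2, the only library of set C in this comparison, 22 families passed, and without replicate 1 of that group 1 passed, the 5' fragments of tRNA-Gly-GCC. Without replicate 1 and without replicate 2 of Dnmt2+/+ ND, the log2 fold changes were -0.04 and -1.28 for tRNA-Glu-CTC, -1.15 and -0.28 for tRNA-Gly-GCC, 1.63 and 6.04 for tRNA-Val-AAC, and 1.495 and 4.45 for tRNA-Lys-CTT. With the set as a term, tRNA-Val-AAC turned to -1.45 and tRNA-Glu-CTC was at -0.01.

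When rRNA and microRNA families were added after seeing the data, 1 of 100 families passed in Dnmt2+/+ sperm. It was let-7f, a member of a microRNA family found in many somatic tissues, with 1071 CPM ± 73.94 on ND and 16060 ± 2628 on HFD (SD, n = 2 each; log2 fold change 3.91 ± 0.60 SE, adjusted p = 0.0226 in edgeR). let-7a and let-7c, the next most abundant members, had log2 fold changes of 3.52 ± 0.72 and 2.72 ± 0.74 SE, and adjusted p of 0.0673 and 0.0846 in edgeR. All 9 members of the let-7 list passed when adjusted over the list alone, and 1 over all families. The 5' part of 28S rRNA was at 71270 CPM ± 42940 on ND and 147500 ± 3574 on HFD (SD, n = 2 each; log2 fold change 1.05 ± 0.51 SE, not passed). 18S, 5.8S and 5S rRNA were at 7574 CPM ± 2287, 10760 ± 834.8 and 4633 ± 948.8 on ND and at 8562 ± 264.6, 12690 ± 2665 and 3729 ± 552.1 on HFD (SD, n = 2 each; not passed). With the sequencing set as a term, no family passed, and let-7f had a log2 fold change of 2.29 ± 0.50 SE and an adjusted p of 0.176 in edgeR. That diet difference rests on the 2 libraries of set C, which also differ in genotype. Without Dnmt2+/+ ND replicate 2, 33 families passed. let-7f missed the threshold without Dnmt2+/+ ND replicate 1, without Dnmt2+/+ HFD replicate 1 and without Dnmt2+/+ HFD replicate 2, while its log2 fold change stayed between 3.73 and 4.06 without any 1 of the 4 libraries.

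In Dnmt2-/- sperm, where the same comparison asks what diet does without the enzyme, let-7f was again the 1 of 100 families that passed. It was at 740.9 CPM ± 157.6 on ND and 9027 ± 6252 on HFD (SD, n = 2 each; log2 fold change 3.61 ± 0.59 SE, adjusted p = 0.0349 in edgeR). All 9 let-7 members passed when adjusted over the list alone, and 1 over all families. 5' fragments of tRNA-Glu-CTC had a log2 fold change of -0.49 ± 0.42 SE, those of tRNA-Gly-GCC -0.30 ± 0.48, and internal fragments of tRNA-SeC-TCA 2.69 ± 1.17. The 5' part of 28S rRNA was at 73800 CPM ± 15000 on ND and 119600 ± 56130 on HFD (SD, n = 2 each; not passed). None of the 34 tRNA families passed (edgeR, lowest adjusted p = 0.284), with 3 at an unadjusted p under 0.05. With the set as a term, let-7f had a log2 fold change of 2.50 ± 0.49 SE and an adjusted p of 0.111 in edgeR, and none of the 100 families passed. This let-7f value rests on the same 2 libraries of set C as that in Dnmt2+/+ sperm. In the separate fit of the 34 tRNA families with the set as a term, 5' fragments of tRNA-Gly-CCC and of tRNA-Val-AAC passed as lower on HFD; tRNA-Val-AAC had a log2 fold change of -4.90 there and 1.76 ± 1.13 SE without the term. tRNA-Glu-CTC turned to 0.77 in that fit and did not pass. let-7f missed the threshold without either Dnmt2-/- ND library and without Dnmt2-/- HFD replicate 1, with log2 fold changes of 3.84, 3.41 and 2.64, and 12 families passed without Dnmt2-/- HFD replicate 2.

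Summed over its 9 members, let-7 was at 3167 CPM ± 1028 on ND and 32370 ± 14930 on HFD (SD, n = 4 each). All 4 HFD libraries exceeded all 4 ND libraries (exact permutation p = 0.0286, the smallest possible, chosen after seeing the data). The 3 HFD libraries of set B held 32690 to 45460 CPM and the HFD library of set C 11390, against 3537 in the ND library of set C. TMM moved the median log2 fold change of the 100 families from 0.74 to 0.10 in Dnmt2+/+ sperm and from 1.75 to 0.30 in Dnmt2-/- sperm. On the TMM scale let-7f was higher on HFD by 2.69 and 2.19 on the log2 scale, and passed in both genotypes.

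Some markers of other cells differed between the sets. The muscle microRNA miR-206 was at 64.7 to 75.3 CPM in the 3 libraries of set B and at most 0.676 elsewhere, and the liver microRNA miR-122 at 44.1 to 99.7 and at most 1.2. miR-1a, also of muscle, was at 375 to 430 CPM in set B and at most 49.8 elsewhere. miR-143, the most abundant of the muscle list, did not follow the sets, with 609.8 to 844.7 CPM in set B and 196 to 1027 elsewhere. miR-200c, an epithelial microRNA, was at 1762 to 2379 CPM in set B, at 755.5 and 251.2 in the ND and HFD libraries of set C, and at 56.35 to 129.6 in set A. miR-200b followed, at 1030 to 1506 CPM in set B, 845.7 and 273.3 in set C and 93.61 to 210.3 in set A, while miR-182 was at 204.3 to 551.7 over all libraries. The leukocyte microRNAs miR-146a, miR-146b and miR-150 reached at most 81.68, 46.04 and 39.98 CPM in any library, endothelial miR-126a 19.21, and liver miR-194 3.443. Of the 9 blood members, 3 were higher in all HFD than in all ND libraries, miR-146a among them. Over all 61 microRNAs, 18 did not overlap between the diets. Liver miR-192 was at 15.7 to 26.22 CPM on ND and 5.919 to 10.67 on HFD. Of the germline and sperm list, miR-10a was at 1102 to 2087 CPM on ND and 2760 to 3363 on HFD, miR-10b at 907.9 to 1735 and 1842 to 2372, and miR-881 at 270 to 1398 over all libraries. None of the epithelial, blood, endothelial, muscle or liver members passed over all families. Adjusted over the list alone, 2 of 5 muscle and 1 of 3 liver members passed in Dnmt2+/+ sperm, 4 of 5 and 1 of 3 in Dnmt2-/- sperm, and none of 8 germline, 10 epithelial, 9 blood and 2 endothelial members in either.

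**Figure D3:**
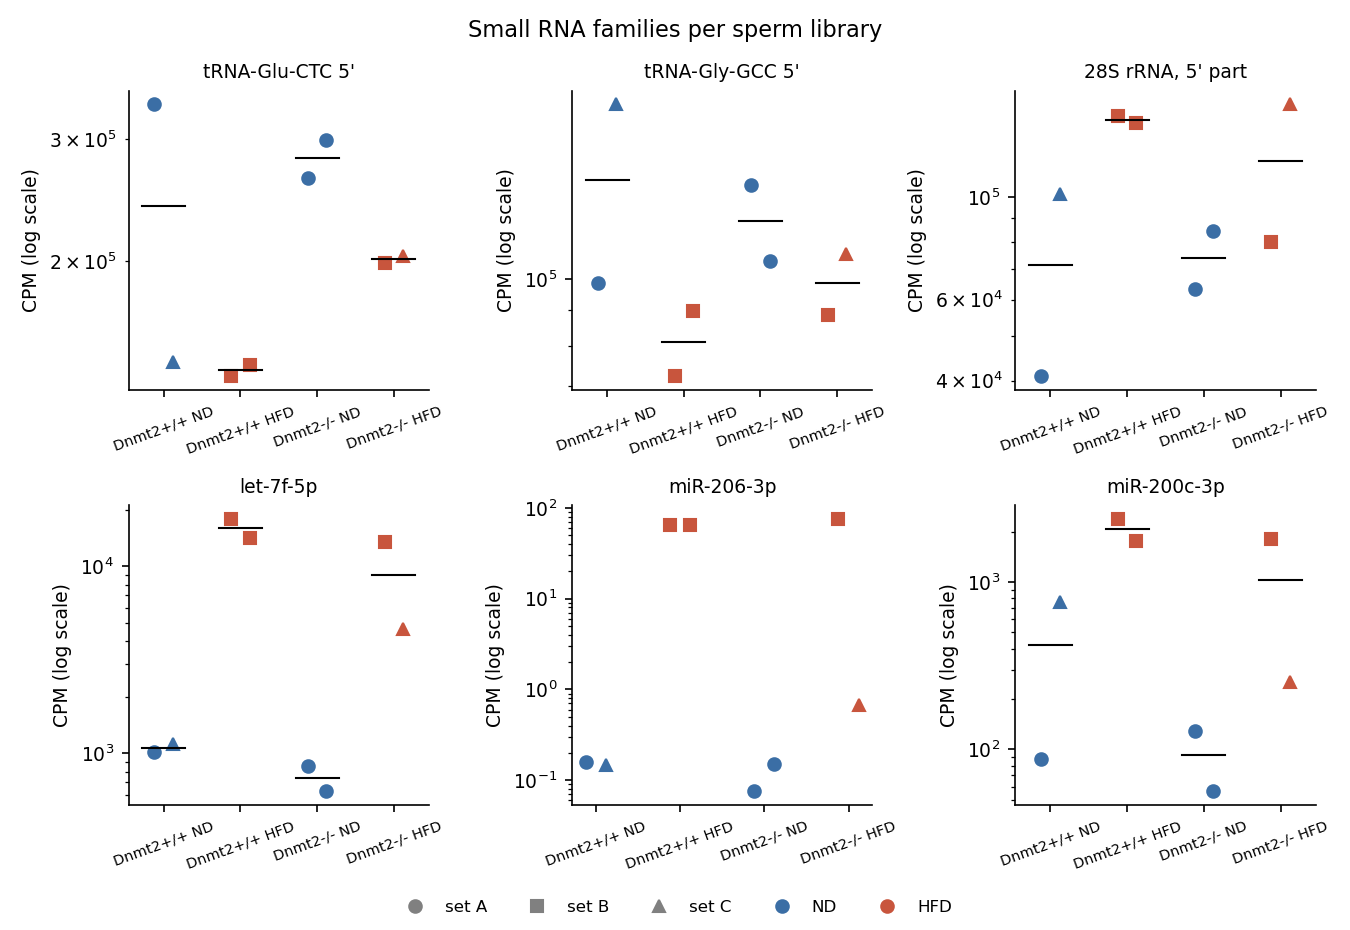
CPM on a log scale of 6 small RNA families in each sperm library, with a line at the mean of each group of 2 except for miR-206. Color gives the diet and shape the set; let-7f is at least 4605 CPM in the 4 HFD libraries and at most 1123 in the 4 ND libraries, while miR-206 exceeds 1 CPM in the 3 libraries of set B alone.

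The comparison of Dnmt2-/- with Dnmt2+/+ sperm asks what loss of the methyltransferase does to the small RNA under each diet. On ND, 5' fragments of tRNA-Gly-GCC had a log2 fold change of -0.19 ± 0.48 SE, those of tRNA-Glu-CTC 0.23 ± 0.42 and those of tRNA-Val-AAC -1.20 ± 1.12. On HFD the values were 0.29 ± 0.48, 0.53 ± 0.42 and -2.01 ± 1.14. The 95% interval of tRNA-Gly-GCC 5' fragments was -1.14 to 0.76 on ND and -0.67 to 1.24 on HFD, which leaves changes of over 2-fold open. None of the 34 tRNA families passed on either diet (edgeR, lowest adjusted p = 0.692 and 0.976), with 1 and 0 at an unadjusted p under 0.05. Without Dnmt2+/+ ND replicate 1, 11 passed on ND. Without Dnmt2+/+ ND replicate 2, and with the set as a term, the 3 values on ND turned direction, to 0.30, -0.26 and 2.28 in the order given. The values of these settings are equal by construction, since each leaves Dnmt2+/+ ND replicate 1 alone to compare with. None of the 100 families passed with rRNA and microRNA added, with 4 and 0 at an unadjusted p under 0.05; 26 passed on ND without Dnmt2+/+ ND replicate 1.

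The sets allow the genotypes to be set side by side under one diet. In set A, on ND, 5' fragments of tRNA-Glu-CTC were at 336900 CPM in the Dnmt2+/+ library and 281200 in the mean of 2 Dnmt2-/- libraries, and those of tRNA-Gly-GCC at 98600 and 121500. In set B, on HFD, tRNA-Glu-CTC was at 138800 CPM in the mean of 2 Dnmt2+/+ libraries and 198500 in the Dnmt2-/- library, and tRNA-Gly-GCC at 81050 and 88680. Fragments of tRNA-Asp-GTC, the best known DNMT2 substrate, were scarce: 5' fragments were at 39.7 to 162.1 CPM and 3' fragments at 81.2 to 538.7 over the 8 libraries. 5' fragments of tRNA-Lys-CTT were at 522 to 2187 CPM. Those of tRNA-His-GTG were at 262.5 to 3259, a level that depends on the match rule, with 12700 exact reads and 63109 with up to 1 mismatch in Dnmt2+/+ ND replicate 1.

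The interaction asks whether diet acts differently without Dnmt2. tRNA-Gly-GCC 5' fragments had an interaction of 0.48 ± 0.68 SE on the log2 scale, tRNA-Glu-CTC 5' fragments 0.30 ± 0.59 and let-7f -0.30 ± 0.76. None of the 34 tRNA families and none of the 100 families passed (edgeR, lowest adjusted p = 0.933 and 0.902), with 0 and 1 at an unadjusted p under 0.05. Without Dnmt2+/+ ND replicate 2, 3 tRNA families passed.

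Among single read sequences, none passed in edgeR in any of the 5 sperm comparisons. At an unadjusted p under 0.05 there were 7734 and 6806 sequences for diet in Dnmt2+/+ and Dnmt2-/- sperm, 1725 and 2167 for genotype on ND and HFD, and 2226 for the interaction. DESeq2 called 1181, 1122, 53, 74 and 37 in the same order. Without Dnmt2+/+ ND replicate 2, edgeR called 6698 for diet in Dnmt2+/+ sperm, and without Dnmt2+/+ ND replicate 1 it called 1662 for genotype on ND and 656 for the interaction. Without Dnmt2-/- HFD replicate 1 it called 320 for genotype on HFD and 135 for the interaction, and without Dnmt2-/- HFD replicate 2 it called 80 for diet in Dnmt2-/- sperm. Each lone library of a group was then assumed to vary like the other groups.

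Most of the sequences with the lowest p were scarce in one group or unmatched, though for genotype on ND not all were. For diet in Dnmt2+/+ sperm they were 3 sequences of 27 and 28 nt without a listed match, absent from both ND libraries and at means of 143, 32.9 and 39.5 CPM on HFD. For diet in Dnmt2-/- sperm, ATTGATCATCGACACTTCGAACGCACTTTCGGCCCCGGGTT, which matches 5.8S rRNA with the change G29T, had a mean of 13.45 CPM on ND and 0.135 on HFD. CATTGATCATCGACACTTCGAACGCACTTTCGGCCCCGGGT, with the change G30T, had 33.4 and 0.135, and one of the unmatched sequences of 27 nt had 0 and 13.2. Positions are counted from the first base of the read. G29T and G30T fall on bases with raised G-to-T rates in set A (384 to 465 and 110 to 114 per 10000). The Dnmt2+/+ library of set A held 0.105 CPM of the G29T sequence, but reads of 41 nt, the length of these sequences, made up 0.0228% of that library and 0.223% and 0.170% of the other 2 of set A. For genotype on ND they included the same G29T sequence (13.45 CPM in Dnmt2-/- and 0.0892 in Dnmt2+/+) and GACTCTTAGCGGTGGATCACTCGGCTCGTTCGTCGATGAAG of 5.8S rRNA with G30T (24.4 and 0.283).

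For genotype on HFD the 3 were unmatched sequences of 26 and 30 nt, with means of 2.94, 4.47 and 887.5 CPM in Dnmt2-/- and 0, 0.0486 and 0 in Dnmt2+/+ sperm. For the interaction they were the G29T sequence, a further 5.8S rRNA sequence and the unmatched sequence of 28 nt already named.

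The 3T3 experiment asks what tsRNA-Gly, a 3' fragment per the labels, does to gene expression in fibroblasts and whether its methylation matters. Of 44374 tested transcripts, 2 passed, both higher with 5 x m5C than with 4 x m5C. ENSMUST00000118875.7 was at 258 and 250.2 CPM with 4 x m5C and at 443.8 and 439.9 with 5 x m5C (log2 fold change 0.76 ± 0.05 SE, adjusted p = 0.05 in edgeR, 0.04996 before rounding). It was at 420.9 and 409.3 CPM in empty cells and 372.6 and 405.6 with unmodified tsRNA-Gly. ENSMUST00000108939.8 had no estimated counts in either 4 x m5C library and 4.37 and 4.4 CPM with 5 x m5C. A floor of 3 counts per library would make this at least 23.8-fold, but counts estimated per transcript do not guarantee such a floor. The same transcript was at 3.59 and 4.09 CPM in empty cells and 4.27 and 4.22 with unmodified tsRNA-Gly, so that for it the 4 x m5C group stands apart. Neither passed when any 1 of the 4 libraries compared was left out, when RLE replaced TMM or with a replicate block, and DESeq2 called 227.

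No transcript passed in edgeR for unmodified, 4 x m5C or 5 x m5C tsRNA-Gly against empty, with 2079, 1934 and 2189 at an unadjusted p under 0.05. DESeq2 called 209, 243 and 119, and edgeR called 2 in each without empty replicate 1. None passed for 4 x m5C or 5 x m5C against unmodified, with 1971 and 2169 at an unadjusted p under 0.05, and DESeq2 called 201 and 153. Among the 6106 transcripts with a log2 CPM of at least 5 in the comparison of unmodified tsRNA-Gly with empty, 98.6% had a 95% interval within 2-fold. Over all 42924 transcripts with an interval it was 40.6%, so changes of over 2-fold stay open for the others.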

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

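All tests in this part were chosen after the results were seen. miR-143, a microRNA of smooth muscle, drew attention because its diet difference took opposite directions in the genotypes: both HFD libraries were below both ND libraries in Dnmt2+/+ sperm and above both in Dnmt2-/- sperm. In Dnmt2+/+ sperm the HFD libraries held 646.1 and 609.8 CPM, close to the 658.3 of ND replicate 1. The difference there rests mostly on ND replicate 2, of set C, at 1027 CPM. The diet difference in Dnmt2-/- minus that in Dnmt2+/+ sperm was 682 CPM, was the 1 such case among 45 values looked at, and was not tested by this rule. In the edgeR fit with rRNA and microRNA families added, no family passed for the interaction.

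Reads that match a tRNA only with 1 inserted or deleted base, which no comparison of exact matches used, made up 11.3% ± 2.69 of sperm reads (SD, n = 8), and 7.08% to 14.7% in single libraries.

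tRNA-Gly-GCC and tRNA-Glu-CTC fragments carried a variant at base 6, counted from the 5' end of the tRNA. In reads that start at base 1, G6T made up 19.8% ± 1.98 (SD, n = 8) of tRNA-Gly-GCC, and reads that lack 1 G of bases 6 and 7 made up 30.1% ± 3.07 (SD, n = 8) of tRNA-Glu-CTC. Sequencing errors at base 6 of the read are argued against: in tRNA-Gly-GCC reads that start at base 2, where the variant is at base 5 of the read, G6T still made up 20.7% ± 2.21 (SD, n = 8), and the median G-to-T rate at base 6 of abundant reads was 0.0632%. Diet or genotype as the source is argued against as well, since the lowest share of either variant in any of the 8 libraries was 17.02%; smaller differences between the groups stay open (lowest exact permutation p of 0.257 in 4 tests). A modified base that may be misread by reverse transcription was not tested.

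let-7 was higher in the HFD libraries, with a median log2 ratio of 3.52 over its 9 members, and 3 explanations were weighed. RNA of epididymal epithelial cells may contribute, since the 10 epithelial microRNAs had a median of 0.958 (-0.175 to 2.59), but all 10 were lower in the HFD than in the ND library of set C (median log2 ratio -1.7), where let-7 was higher. A difference between the sequencing sets could account for part, and the HFD and ND libraries of set C still had a median let-7 log2 ratio of 1.7, above the largest of 0.689 between libraries of the same set and diet; these are only 2 libraries. Diet stays open too: with the set as a term, the let-7f log2 fold change in Dnmt2+/+ sperm was 2.29 and no longer passed. That value rests on the same 2 libraries of set C and is no further evidence. Between sets A and B, diet and set cannot be told apart for let-7. Inside set C, diet cannot be told apart from genotype or from variation between single libraries.

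Of 102 small RNA families, 23 did not overlap between the 4 ND and 4 HFD libraries, where chance gives 2.86% per family. 2 of the 35 splits of the libraries gave at least as many, so chance is not excluded. The highest other split, which exchanges Dnmt2+/+ ND replicate 2 and Dnmt2-/- HFD replicate 2, had 42 and points to a structure of the samples. Both splits place all of set A against all of set B, with 1 library of set C on each side. The sequencing sets may thus lie behind both counts, but they do not account for 42 against 23. The lowest correlation between libraries of the same set and different groups was 0.849, above the highest of 0.765 between libraries of the same group and different sets. The sequences correlated include reads with the errors that define the sets, which can raise r within a set. Labels exchanged between the 2 libraries of set C stay open, with 1 of the 2 closer to the opposite group. The Dnmt2+/+ ND library had r of 0.8297 with Dnmt2-/- HFD replicate 1 and 0.6059 with its own group. The Dnmt2-/- HFD library had 0.7054 with Dnmt2+/+ ND replicate 1 and 0.7654 with its own. These values cannot decide the question, since the libraries compared with lie in sets A and B. Both libraries of set C were closer to set B (0.8038 to 0.8297 and 0.7427 to 0.7654) than to set A (0.6059 to 0.6861 and 0.7054 to 0.7334). Diet stays open too, with a lowest adjusted p of 0.176 in edgeR in Dnmt2+/+ sperm with the set as a term.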

How the results depend on the processing

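Of the settings fixed before the data were examined, none took a share of sperm reads past its threshold or turned its direction; all lengths as denominator changed nothing, since every read was within the length limits. The set as a term, the removal of set C, the match with 1 edit and the families with rRNA and microRNA were chosen after seeing the data. Without set C, all ND libraries are of set A and all HFD libraries of set B. Diet counts without set C thus compare the sets as much as the diets. The 3T3 gene lists and their alternatives were not run, because no transcript had a gene name.

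For sperm sequences (diet in Dnmt2+/+, diet in Dnmt2-/-, genotype on ND, genotype on HFD, interaction), a total count of at least 10 gave 1818, 2240, 107, 204 and 227 calls with 187033 sequences tested, and DESeq2 gave 1181, 1122, 53, 74 and 37. The set as a term gave 24, 32, 78, 70 and 26, and removal of both libraries of set C gave 14331, 8577, 143, 149 and 56. Leaving out 1 library gave 1 to 6698, 0 to 80, 0 to 1662, 0 to 320 and 0 to 656.

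For tRNA families the set as a term gave 2 calls for diet in Dnmt2-/- sperm, and removal of set C gave 24 and 16 for diet in the genotypes. Leaving out 1 library gave 0 to 22, 0 to 0, 0 to 11, 0 to 0 and 0 to 3. With rRNA and microRNA added, diet in Dnmt2+/+ and Dnmt2-/- sperm had 15 (11 higher, 4 lower) and 10 (10 higher, 0 lower) calls with TMM, 0 and 0 with the set as a term, and 66 and 61 without set C. Leaving out 1 library gave 0 to 33, 0 to 12, 0 to 26, 0 to 0 and 0 to 0.

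In 3T3 cells (unmodified, 4 x m5C and 5 x m5C against empty, 4 x m5C and 5 x m5C against unmodified, 5 x m5C against 4 x m5C), DESeq2 gave 209, 243, 119, 201, 153 and 227, and a total count of at least 1 gave 21, 27, 2, 23, 16 and 34. RLE gave 0 for the last. Leaving out 1 library gave 0 to 2 for each comparison with empty, where the 2 came without empty replicate 1, and 0 to 0 for the others. The cause of these differences was not tested.

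Replicate numbers did not pair the libraries (correlation of deviations -0.276 to 0.224 in sperm, -0.0258 to 0.0656 in 3T3). With a replicate block there were 0 calls for 5 x m5C against 4 x m5C, in place of 2. The other 5 comparisons of 3T3 transcripts and the 5 each of sperm sequences and of tRNA families had 0 calls with and without it, and families with rRNA and microRNA added were not run with a block. Block permutation of shares left the tsRNA diet difference at -12.3 points, with an adjusted p of 0.111. The block does not change the difference, and this permutation cannot go below p = 0.0556, so no share could pass.

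When 1 library was left out, no share difference turned direction, though those between genotypes moved by over 1.5 times. For HFD minus ND the tsRNA share ran from -14.2 to -10.6 points, the rRNA-derived share from 5.42 to 8.53, the microRNA share from 2.74 to 4.18, and reads of 30 to 34 nt from -14.1 to -11.3. For genotype they ran from 1.7 to 8.78, -4.16 to -0.314, -2.56 to -0.622 and 2.81 to 8.45.

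Some named tRNA families turned direction. With the set as a term, 5' fragments of tRNA-Val-AAC had a log2 fold change of -1.45 for diet in Dnmt2+/+, -4.90 for diet in Dnmt2-/- and 2.28 for genotype on ND, tRNA-Glu-CTC had 0.77 for diet in Dnmt2-/- and -0.26 for genotype on ND, and tRNA-Gly-GCC had 0.30 for genotype on ND. The last 3 genotype values on ND were 2.28, -0.26 and 0.30 without set C and without Dnmt2+/+ ND replicate 2 as well. That follows by construction, since each of these settings compares the Dnmt2-/- ND libraries with Dnmt2+/+ ND replicate 1 alone. TMM gave -0.14 for tRNA-Glu-CTC for genotype on ND. Without Dnmt2-/- HFD replicate 1, tRNA-Val-AAC had -0.49 for diet in Dnmt2-/-. Without 1 library, genotype on ND ran from -0.26 to 0.98 for tRNA-Glu-CTC, -0.56 to 0.30 for tRNA-Gly-GCC and -2.36 to 2.28 for tRNA-Val-AAC, and diet in Dnmt2-/- from -0.49 to 2.92 for tRNA-Val-AAC.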

Other observations

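The ends of the fragments were chosen for this part after the data were seen. The 5' part of 28S rRNA was the most abundant rRNA family, and 95.5% to 98.4% of its reads in a library started at base 1 of the mature rRNA as listed. tRNA-Gly-GCC fragments started at base 1 in 97.6% to 99.2% of reads and ended mostly at base 30 or 31; base 31 took 27.9% to 64.9% of reads and base 30 took 14.45% to 41.9%. tRNA-Glu-CTC fragments started at base 1 in 94.9% to 99.15% of reads, and in Dnmt2-/- HFD replicate 1 a share of 4.045% started at base 2, against at most 0.854% in the other 7 libraries. miR-148a was the most abundant microRNA listed in all 4 ND libraries, at 14800 CPM in Dnmt2+/+ ND replicate 1, and lay between 3318 and 5710 CPM in the other 7 libraries.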
